A study of Rattus norvegicus with 12 samples.

How the data were processed

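The series holds 12 samples of Sprague Dawley rat heart tissue at 2 postnatal ages, 6 of RNA pulled down with an antibody against N6-methyladenosine (m6A, a methyl mark on adenosine in RNA) and 6 of input RNA. Each age has 3 input libraries and 3 pull-down libraries. Input RNA is the RNA before the pull-down and measures transcript levels. The table used here has columns for the 6 input libraries, so the pull-down libraries, the pull-down over input ratio within each age and the change of that ratio between ages were not analysed here.

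Per the labels' protocols, total RNA was extracted from tissue, ribosomal RNA was removed and cDNA was made by the SMART method before PCR amplification. The submitters' processing notes name HISAT2, HOMER 4.10 and the rat build rn5, with no role or order given. The counter, the gene annotation and the authors' test are not given in the sources used here. Many gene names of the table are clone names of a style used with a later rat assembly than rn5, so no coordinates are printed. Whether reads were counted by strand is also not given, so genes with an overlapping antisense partner are uncertain.

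The deposited values are FPKM (reads scaled by gene length and by the library total), 1 column per library for 16898 genes, as the values themselves show. Within each gene the 6 deposited FPKM values were whole multiples of the value of 1 read. Whole reads were recovered for 100% of the 16898 genes at a relative tolerance of 2e-13, and 976 genes needed a shared factor. Library totals recovered in this way ran from 13489816 to 16297533 reads, of which 99.51% to 99.61% fell in the listed genes. In a gene of 1 kb, 1 read was worth 0.0614 to 0.0741 FPKM. PCR reads without molecular identifiers are not independent molecules, so read numbers give counting error only. The recovery was tested on simulated data, where 100% of 1994 genes came back up to a common factor.

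The authors' deposited table also gives a log2 fold change, a p-value and an adjusted p-value per gene. Its log2 fold change is older over day 0 and lies 0.12 above the log2 ratio of mean FPKM at the median, for genes above 1 FPKM at both ages. Its adjusted p equals the Benjamini-Hochberg value over 15205 rows, and the other 1693 rows hold 1.

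The column headers and the labels disagree on the age of the older hearts. The labels give postnatal day 0 and day 7, whereas the headers read OD and 10D. OD was taken as day 0. The 10D columns were taken as the day 7 input samples because no other age is left in the labels. These samples are called older hearts throughout, and no exact age is claimed for them. Library numbers were taken from the column names. The labels do not say that replicates came from separate animals or litters, so p-values measure the spread between these samples, which may be technical.

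Because FPKM values are not counts, they were tested on the log2(FPKM + 1) scale with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. The 13117 genes with a mean of at least 1 FPKM over the 6 libraries were tested and 3781 were left out. Every log2 fold change is older minus day 0 on that scale, which understates changes of low genes. Values are given as mean FPKM ± SD with n = 3 libraries per age. Adjusted p-values for genes are limma's.

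Before the data were examined, 44 gene lists, a panel of 15 genes, the tests and most alternatives were fixed. Of 827 listed symbols 716 were found, and the other symbols include alternative spellings of found genes. Where several genes share a symbol, that with the highest mean FPKM was used. Lists with at least 3 tested genes (39 lists) were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. The latter setting also tests on the few residual degrees of freedom of the libraries, so a call lost there does not by itself show correlated genes. Camera asks whether a list differs from the other genes. limma's fry was run as well. It asks whether the genes of a list move on balance in one direction, without comparing them with other genes. List medians were also ranked among 10000 random lists matched on mean expression.

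Named genes followed a rule fixed beforehand. It takes the panel, then the 6 highest and 6 lowest log2 fold changes among genes past the threshold with a symbol, a mean of at least 5 FPKM at the higher age and no overlap between ages. For each list it adds up to 2 called members at either end with a mean of at least 1 FPKM. The result of 1 gene taken by this rule, and of the marker list that holds it, is not reported here. Other genes named to list the called members of a group, and markers of skeletal muscle and lung, were named after their values were seen.

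The fit was tested on simulated reads for the comparison of older with day 0 hearts, with 13004 genes fitted. At a 2-fold change 31 of 97 genes were called (32%), and at a 4-fold change 66 of 100 were called (66%). Of 12777 unchanged genes 4 were called. Far fewer genes were changed there than were called in the data, genes were drawn independently and no library stood apart. These shares therefore need not hold for the real comparison. Alternatives covered the scaling, the filter, the pseudocount, the threshold, the mean-variance trend, a block on the replicate number and each library left out. Those added after seeing the data were centring on the median gene, limma's voom on the recovered reads, the authors' adjusted p and protein-coding genes alone. Figures were drawn with matplotlib 3.10.9.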

Results

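Transcript levels were measured by sequencing input RNA from rat heart tissue at postnatal day 0 and at an older age, with 3 libraries each. The older hearts are day 7 in the sample labels and 10D in the headers of the deposited table. Library totals were 14613968, 13489816 and 16297533 reads at day 0 and 15868418, 16097510 and 15027254 reads in the older hearts. The comparison asks how the transcript levels of the heart differ between the newborn and the older age. Such levels are the background against which m6A marks in the same tissue would be read.

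Older hearts had far more Myom2 and far less Myl4 RNA than newborn hearts. Myom2 encodes an M-band protein of the sarcomere and rose from 117 ± 33.8 to 1256 ± 103 FPKM (SD, n = 3; log2 fold change 3.45, SE 0.20, limma adjusted p = 0.000339). Myl4, the atrial and embryonic essential myosin light chain, fell from 609 ± 132 to 75.7 ± 16.6 FPKM (SD, n = 3; log2 fold change -2.99, limma adjusted p = 0.000492). The splicing regulator Rbfox1 rose from 0.413 ± 0.298 to 21.9 ± 2.32 FPKM, and Ddit4l2 from 0.538 ± 0.539 to 23.9 ± 6.59 FPKM (SD, n = 3). Also rising were the lipoxygenase gene Alox15 (log2 fold change 3.70), Akr1c15 (3.45) and C1qtnf9 (3.38), whose product is secreted. On the lower side stood Cdhr1 (-3.96), the transporter gene Slc16a12 (-3.86), Fignl1 (-3.20) and the growth factor gene Fgf18 (-3.17, with a limma adjusted p of 0.0518 without older replicate 1). Ntsr2, a neurotensin receptor gene, was listed at 0 in all 3 older libraries against 10.7 ± 5.49 FPKM at day 0 (SD, n = 3; limma adjusted p = 0.00373).

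Of 13117 genes tested, limma called 462 higher and 752 lower in older hearts, and 273 and 315 of these changed at least 2-fold. Among protein-coding genes 436 were higher and 714 lower. The 2 ages did not overlap in 4264 genes (32.5%), where chance gives 10%. The median gene stood at -0.11, so list medians below are given relative to it. The split of 38.1% higher turned to 55.3% (608 higher, 492 lower) after centring on the median gene and to 56.4% (620 and 479) after quantile normalization, and the authors' deposited table has 1058 higher and 934 lower at an adjusted p under 0.05. With 1 library left out the total of 1214 fell to between 363 and 521 for each library except day 0 replicate 3, without which 484 were higher and 646 lower. A limma adjusted p given below for a gene without 1 library is the highest of the 6 such values, except where day 0 replicate 3 is named. The calls of Tnnt1, Orc6, Ucp3, Pfkfb2, Mt-cyb and Mt-co1 were lost with any 1 of the 6 libraries left out. Those of Gins1, Meis2, Rplp1, Prc1, Ndufb8, Cldn5, Eno3 and Junb were lost with 5 of the 6 left out in turn, and those of Ccnb1, Myh6, Rpl6, Dlk1, Lum, Rgs5, C7, Tfrc and Fgf1 with 4. Genes named outside the naming rule were not followed in this way through all 6 libraries. Where a list called by camera did not pass in limma's fry, the fry value is given, and the other called lists described had fry adjusted p from 0.00156 to 0.0309. Of the random lists matched on mean expression, 6% had a lower median than the m6A readers, 81.3% than antigen presentation and 95.2% than the neuregulin list. For the other called lists described, that share was at most 0.92% for lower lists and at least 98.7% for higher lists.

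**Figure D1:**
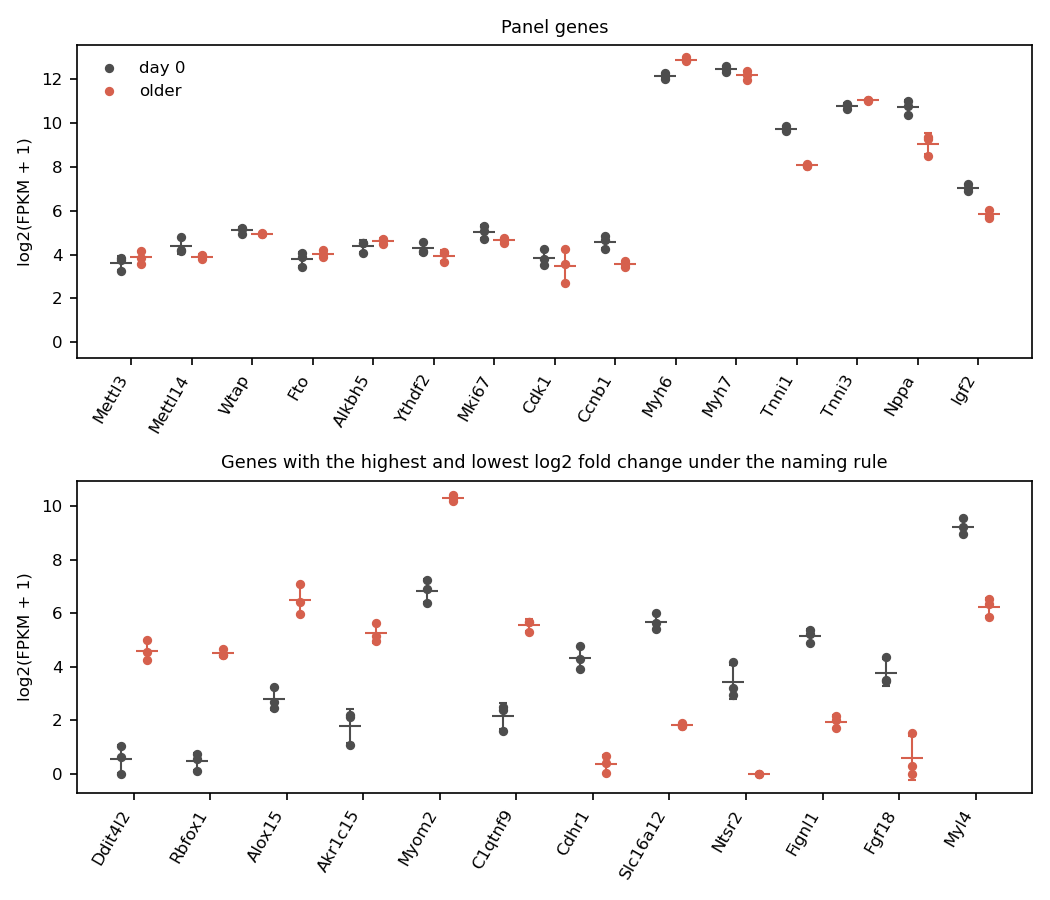
Each point is 1 input library, in log2(FPKM + 1), with day 0 in grey and older hearts in red, and the bars give mean ± SD (n = 3). Panel genes are above and the 12 genes with the highest and lowest log2 fold changes under the naming rule are below, where the ages do not overlap.

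Genes that mark the fetal heart fell as a list. All 16 tested genes of the fetal cardiac programme had negative log2 fold changes, 6 fell (8 adjusted over the list alone), and the list median was -0.75 relative to all genes (camera adjusted p = 1.68e-06). That list call was lost in camera with adjusted p = 0.323 with an estimated correlation. Tnni1, the slow skeletal troponin I of the fetal heart, fell from 854 ± 74.5 to 265 ± 11.96 FPKM (SD, n = 3; log2 fold change -1.68, limma adjusted p = 0.000338). Nppa, which encodes atrial natriuretic peptide, fell from 1711 ± 389 to 546 ± 159 FPKM (SD, n = 3; -1.67, limma adjusted p = 0.0106, and 0.0540 without day 0 replicate 1). The smooth muscle actin gene Acta2 (-1.68) and Myl9 (-1.74) fell as well. Tnnt1, slow skeletal troponin T, was called at -2.27, but day 0 replicate 3 held 36.7 FPKM against 15.7 and 14.2 in the other day 0 libraries, and the limma adjusted p was 0.0956 without that library and 0.129 without older replicate 1.

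The adult myosin gene Myh6 rose from 4499 ± 449 to 7572 ± 582 FPKM (SD, n = 3; log2 fold change 0.75, limma adjusted p = 0.0118, and 0.0823 without day 0 replicate 2). Its fetal counterpart Myh7 stood at 5633 ± 580 and 4618 ± 618 FPKM (limma adjusted p = 0.237), and Tnni3, cardiac troponin I, at 1741 ± 145 and 2075 ± 44.6 FPKM (limma adjusted p = 0.151; SD, n = 3). In the mature cardiomyocyte list 4 of 18 tested genes rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.23 relative to all genes (camera adjusted p = 0.0328, adjusted p = 0.472 with an estimated correlation, fry adjusted p = 0.142). Ckmt2, mitochondrial creatine kinase of muscle, rose from 18.1 ± 11.4 to 136 ± 33.5 FPKM (SD, n = 3; log2 fold change 2.98), with Mb and Ldhb also higher. The cardiac actin gene Actc1 (-0.77) and Ldb3 (-0.65), a Z-disc protein gene, were the members that fell. The list's call did not hold without day 0 replicate 2, older replicate 2 or older replicate 3, with camera adjusted p up to 0.0841.

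Calcium and transcription factor genes moved in both directions. Slc8a1, the sodium-calcium exchanger, fell from 668 ± 33.8 to 196 ± 12.8 FPKM (SD, n = 3; log2 fold change -1.77, limma adjusted p = 0.000224), whereas Hrc, a calcium-binding protein of the sarcoplasmic reticulum, rose by 1.38. Of 23 tested calcium handling and ion channel genes 3 rose and 4 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.443). Among 21 cardiac transcription factors 1 rose and 6 fell (3 and 9 adjusted over the list alone, camera adjusted p = 0.242, fry adjusted p = 0.0185 as lower). Irx4, a ventricular homeobox factor, fell by 1.88 and Tbx20 by 1.69 on the log2 scale. Srf, Myocd, Gata6 and Gata4 were also lower, with a limma adjusted p of 0.0670 for Gata6 without day 0 replicate 3. Thrb, a thyroid hormone receptor, was called higher at 2.25, with limma adjusted p of 0.0610 without older replicate 2.

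DNA replication and mitosis genes were lower as lists. Of 30 tested replication genes 7 fell and 17 fell adjusted over the list alone, with a median of -0.70 relative to all genes (camera adjusted p = 4.4e-06, adjusted p = 0.323 with an estimated correlation). The called genes were Gins1 (-1.81), Orc6 (-1.38), Rrm1 and the helicase subunits Mcm2, Mcm3, Mcm5 and Mcm6. Mcm3 had a limma adjusted p of 0.0699 without day 0 replicate 3. Gins1 reached a limma adjusted p of 0.122 without older replicate 1 and Orc6 0.137 without older replicate 3. Of 29 mitosis genes 2 fell, over all genes as over the list alone, and the median was -0.44 relative to all genes (camera adjusted p = 0.000194, adjusted p = 0.455 with an estimated correlation, fry adjusted p = 0.0796). Without day 0 replicate 3 the list median, not taken relative to all genes, was -0.31 instead of -0.55. The called genes were the cyclin gene Ccnb1, from 23.2 ± 4.64 to 11.02 ± 1.16 FPKM (SD, n = 3; log2 fold change -0.997, limma adjusted p = 0.0201, and 0.0841 without older replicate 2), and Prc1 (-0.87, limma adjusted p = 0.0354, and 0.126 without older replicate 2). The proliferation marker Mki67 stood at 32.4 ± 6.70 and 24.0 ± 1.94 FPKM (limma adjusted p = 0.201), and Cdk1 at 13.8 ± 3.74 and 11.3 ± 6.26 FPKM (limma adjusted p = 0.597; SD, n = 3). Cdkn1a, the inhibitor p21, rose from 7.998 ± 2.19 to 27.9 ± 5.20 FPKM (SD, n = 3; 1.70, limma adjusted p = 0.00673), while Meis2 was called lower (-0.60, limma adjusted p = 0.0482, and 0.150 without older replicate 2), and the list of 15 was not called (3 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.242).

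Imprinted growth genes of fetal tissue were lower in older hearts. Of 14 tested, 5 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.49 relative to all genes (camera adjusted p = 0.00744, adjusted p = 0.385 with an estimated correlation). Igf2, a fetal growth factor, fell from 131 ± 15.6 to 56.3 ± 7.72 FPKM (SD, n = 3; log2 fold change -1.21, limma adjusted p = 0.00383). Plagl1 fell by 1.55, and Dlk1 was called at -2.09 (limma adjusted p = 0.0202, and 0.0909 without older replicate 1). The member that rose was Dcn, which encodes the matrix proteoglycan decorin and is also in the fibroblast list.

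**Figure D2:**
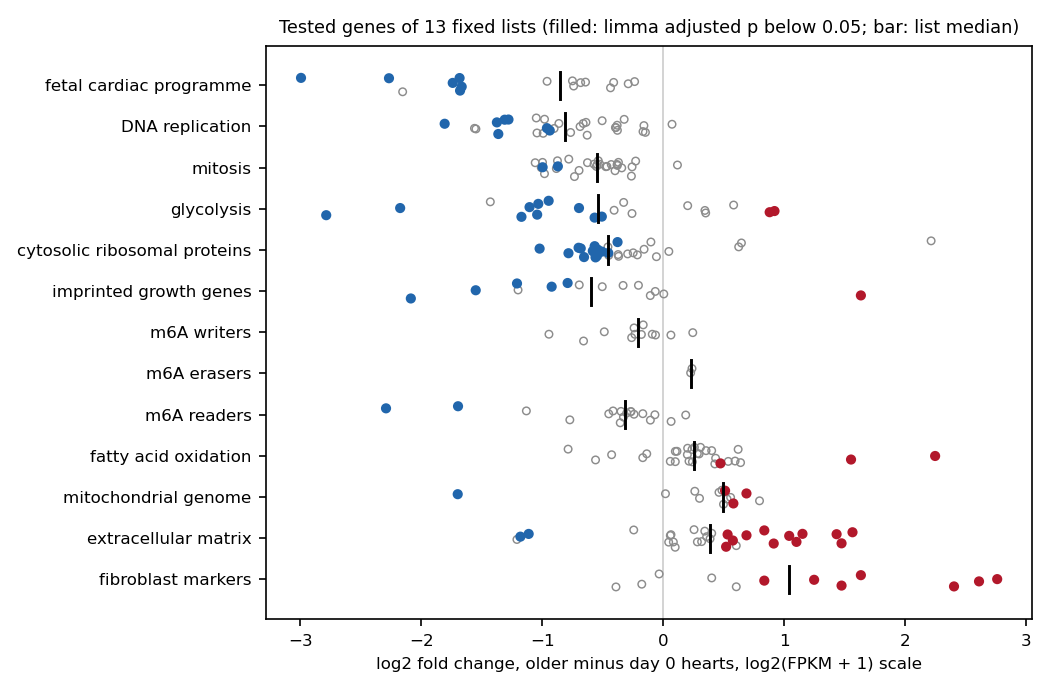
Each point is 1 tested gene of 13 lists, at its log2 fold change of older minus day 0 hearts on the log2(FPKM + 1) scale. Filled points passed limma's adjusted p of 0.05 (red higher, blue lower), open points did not, and bars are list medians. No m6A writer or eraser is filled, whereas 7 fibroblast markers and 14 cytosolic ribosomal protein genes are.

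Glycolysis genes were lower and fatty acid oxidation genes higher as lists. In glycolysis 10 of 20 tested genes fell and 2 rose (12 and 4 adjusted over the list alone), with a median of -0.43 relative to all genes (camera adjusted p = 0.00355, adjusted p = 0.323 with an estimated correlation). Slc16a3, a lactate transporter gene, fell from 10.3 ± 2.21 to 0.705 ± 0.631 FPKM (SD, n = 3; log2 fold change -2.79, limma adjusted p = 0.00552). The glucose transporter gene Slc2a1 fell from 55.6 ± 19.7 to 11.1 ± 1.81 FPKM (SD, n = 3; -2.17, limma adjusted p = 0.00484). The muscle enolase gene Eno3 (0.92) and Pfkfb2 (0.88) were the 2 called higher, with limma adjusted p up to 0.0888 for Eno3 without older replicate 2 and 0.130 for Pfkfb2 without older replicate 1. Of 29 fatty acid oxidation genes 3 rose, over all genes as over the list alone, and 24 had positive log2 fold changes, with a median of 0.37 relative to all genes (camera adjusted p = 2.18e-05, adjusted p = 0.401 with an estimated correlation, fry adjusted p = 0.119). Pdk4, which limits the use of pyruvate within the mitochondrion, rose from 109 ± 4.65 to 522 ± 64.2 FPKM (SD, n = 3; 2.25, limma adjusted p = 0.000223). Ucp3 (1.55, limma adjusted p = 0.0244) and Acadm were the others, and Ucp3 reached 0.0803 without older replicate 1. Without day 0 replicate 3 the list had 4 higher genes and 1 lower, and its median, not taken relative to all genes, was 0.07 instead of 0.26.

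Transcripts of the mitochondrial genome took more of the reads in older hearts. Their protein genes held 7.20% to 8.99% of reads in the day 0 libraries and 10.5% to 12.03% in the older libraries. Of 13 tested genes 3 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000194, adjusted p = 0.401 with an estimated correlation, fry adjusted p = 0.0843). Those called higher were Mt-co1 (0.69), Mt-cyb (0.58) and Mt-nd5 (0.51), and without day 0 replicate 3 none of the 3 passed (limma adjusted p of 0.106, 0.0777 and 0.107) and the list had 0 higher and 1 lower. The limma adjusted p was 0.166 for Mt-co1 without older replicate 2 and 0.118 for Mt-cyb without day 0 replicate 2. Mt-nd6, the protein gene on the opposite strand of the mitochondrial genome, fell from 5638 ± 807 to 1796 ± 577 FPKM (SD, n = 3; -1.70, limma adjusted p = 0.00896, and 0.0567 without day 0 replicate 2). The counting strand is not known, so its reads cannot be assigned firmly. Nuclear genes of oxidative phosphorylation were not called as a list (1 of 34 fell, 0 adjusted over the list alone, camera adjusted p = 0.106), and that 1 was Ndufb8 (-0.52, with a limma adjusted p of 0.123 without older replicate 1). Without day 0 replicate 3 that list had 2 lower genes.

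None of the 12 tested m6A writer genes and neither of the 2 erasers passed the threshold, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 limma gave 2 writers and 0 erasers, and voom called 1 writer, Mettl5, an enzyme that methylates ribosomal RNA. Mettl3, the catalytic subunit of the writer complex, stood at 11.5 ± 2.65 FPKM at day 0 and 13.8 ± 3.11 in older hearts (SD, n = 3; log2 fold change 0.24, limma adjusted p = 0.562). Its partner Mettl14 was at 20.5 ± 5.79 and 14.0 ± 1.14 FPKM (SD, n = 3; -0.49, limma adjusted p = 0.190), and Wtap at 33.7 ± 3.83 and 29.8 ± 0.288 FPKM (SD, n = 3; -0.17, limma adjusted p = 0.462). The eraser genes Fto (0.24, limma adjusted p = 0.513) and Alkbh5 (0.23, limma adjusted p = 0.450) and the reader gene Ythdf2 (-0.33, limma adjusted p = 0.343) did not pass either. Of 18 reader genes 2 fell and 5 fell adjusted over the list alone (median -0.21 relative to all genes, with 6% of the matched random lists lower still, camera adjusted p = 0.00287, adjusted p = 0.323 with an estimated correlation). These 2 were Igf2bp1, from 12.9 ± 4.81 to 1.85 ± 1.08 FPKM (SD, n = 3; -2.29, limma adjusted p = 0.0107, and 0.0542 without older replicate 1), and Igf2bp3, from 16.0 ± 1.43 to 4.32 ± 1.07 FPKM (SD, n = 3; -1.70, limma adjusted p = 0.00484). Both encode RNA-binding proteins of fetal tissues that are also counted as m6A readers.

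Fibroblast markers and matrix genes were higher in older hearts. Of 12 fibroblast markers 7 rose (8 adjusted over the list alone) and the median was 1.15 relative to all genes (camera adjusted p = 2.21e-06, adjusted p = 0.323 with an estimated correlation). Dcn rose from 67.1 ± 13.6 to 208 ± 5.80 FPKM (SD, n = 3; log2 fold change 1.63, limma adjusted p = 0.00153), and Pdgfra, a receptor of fibroblasts, by 1.25. Mfap5 (2.76) and Pi16 (2.61) had the highest log2 fold changes, with limma adjusted p of 0.0812 and 0.0534 without older replicate 2. Of 29 extracellular matrix genes 12 rose and 2 fell (14 and 2 adjusted over the list alone; median 0.50 relative to all genes, camera adjusted p = 1.88e-06, adjusted p = 0.401 with an estimated correlation, fry adjusted p = 0.0796). Fbln1 rose by 1.56 and the collagens Col1a1, Col3a1, Col14a1 and Col15a1 were among the others. The provisional matrix genes Vcan (51.4 ± 1.77 to 22.2 ± 1.74 FPKM; SD, n = 3) and Fbn2 fell, at log2 fold changes of -1.18 and -1.11. Lists and marker lists share members, with Col1a1 and Lum in both of these.

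Markers of other cell types were called in both directions. The endothelial list had 2 of 12 genes higher (3 adjusted over the list alone, camera adjusted p = 0.0223, adjusted p = 0.323 with an estimated correlation, fry adjusted p = 0.0654), namely Cdh5 (0.81) and Cldn5 (1.01), with limma adjusted p of 0.0574 and 0.137 without older replicate 2. Its camera adjusted p was 0.0805 without day 0 replicate 1, its call was also lost without older replicate 2, and it had 1 higher gene without day 0 replicate 3. Among 12 pericyte and smooth muscle markers 3 fell and 1 rose (3 and 3 adjusted over the list alone, camera adjusted p = 0.941). Their fry adjusted p was 0.0286 as lower, although the median was 0.03 relative to all genes. Cnn1, the smooth muscle calponin, fell from 32.2 ± 11.8 to 3.27 ± 0.659 FPKM (SD, n = 3; -2.91, limma adjusted p = 0.00176), whereas the pericyte gene Rgs5 was called higher at 1.85 (limma adjusted p = 0.0132, and 0.0725 without older replicate 1). In limma no macrophage marker passed (0 of 11, 1 at an unadjusted p under 0.05, 0 with voom, camera adjusted p = 0.994). The median and mean log2 fold changes of these markers, not taken relative to all genes, were -0.04 and -0.14, whereas camera's direction was up. Cardiomyocyte markers were not called as a list (1 of 11 rose and 2 fell, also adjusted over the list alone, camera adjusted p = 0.610). In the 6 epicardial markers 0 passed over all genes and 1 fell adjusted over the list alone, at an unadjusted p under 0.05 and with limma's voom (camera adjusted p = 0.443).

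Cytosolic ribosomal protein genes were lower. Of 28 tested 14 fell (17 adjusted over the list alone) and 0 rose, with a median of -0.34 relative to all genes (camera adjusted p = 3.47e-06, adjusted p = 0.323 with an estimated correlation). Rplp1 fell from 1000 ± 96.8 to 501 ± 132 FPKM (SD, n = 3; log2 fold change -1.02, limma adjusted p = 0.0163, and 0.0779 without older replicate 2) and Rpl6 from 223 ± 16.9 to 130 ± 23.6 FPKM (SD, n = 3; -0.78, limma adjusted p = 0.0195, and 0.0840 without day 0 replicate 2). The shared reads of these genes with processed pseudogenes are unknown. Among 12 heat shock genes 4 fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.0332, adjusted p = 0.323 with an estimated correlation). The mitochondrial chaperone gene Hspd1 fell from 236 ± 5.47 to 129 ± 7.31 FPKM, and the co-chaperone gene Bag3 rose from 59.3 ± 0.915 to 121 ± 4.21 FPKM (SD, n = 3). That list's camera adjusted p was 0.0567 without day 0 replicate 1, its call was also lost without older replicate 2, and without day 0 replicate 3 it had 2 lower genes and 1 higher. Of 17 immediate early genes, which respond to handling, 2 rose (3 adjusted over the list alone, camera adjusted p = 0.0736), namely Fosl2 (1.81) and Junb (1.95, limma adjusted p = 0.0277, and 0.118 without older replicate 2).

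Day 0 replicate 3 stood apart from the other libraries in holding transcripts of other tissues. Myh8, the neonatal skeletal myosin, was at 83.8 FPKM there and at most 0.108 elsewhere. The fast skeletal troponin genes Tnni2 (69.4 FPKM) and Tnnc2 (67.2 FPKM) were at most 2.39 and 0.296 in the other 5 libraries. Sftpc, the lung surfactant protein C gene, had 343 reads there and 0 elsewhere, and Sftpb had 235 and 0. The skeletal muscle list had 0 of 8 tested genes called (0 adjusted over the list alone, camera adjusted p = 0.318), as had the lung list with 3 tested (camera adjusted p = 0.629), and at an unadjusted p under 0.05 limma and at an adjusted p of 0.05 voom also gave 0 in either list. Without this library the skeletal muscle list had 1 higher gene, Tnnt3, and its median log2 fold change went from -1.99 to -0.15 (camera adjusted p = 0.814). The fetal programme and DNA replication lists each had 6 lower genes without it, and both stayed called (camera adjusted p = 4.21e-05 and 5.25e-06). The loss of both calls with an estimated correlation (camera adjusted p = 0.323) was seen with all libraries and is a separate setting. The authors' deposited table calls Myh3, an embryonic skeletal myosin gene, lower in older hearts (adjusted p = 0.00226), with 53.6 FPKM in day 0 replicate 3 and at most 2.48 elsewhere.

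**Figure D3:**
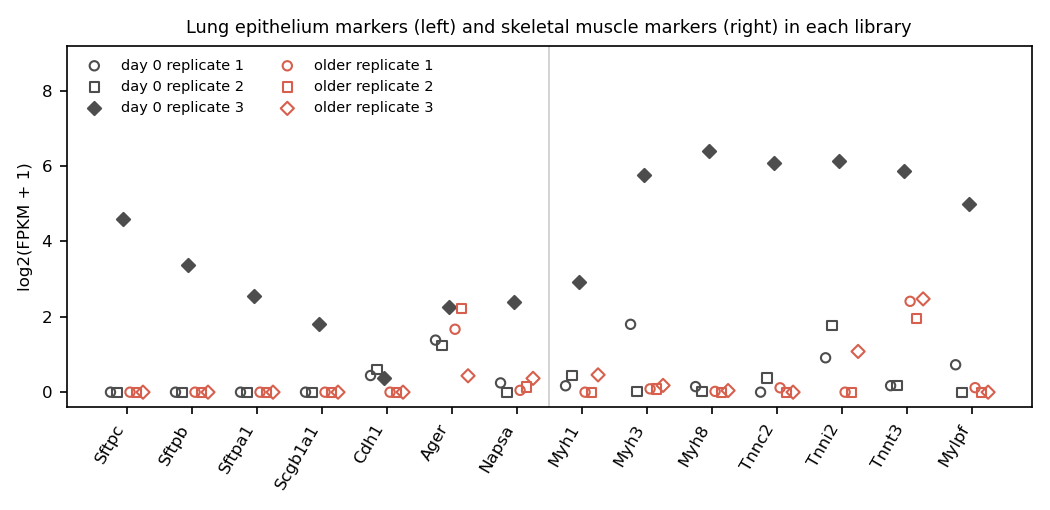
Each point is 1 library, in log2(FPKM + 1), for 7 lung epithelium and 7 skeletal muscle markers with at least 10 reads in all. Day 0 replicate 3 (filled diamonds) is the highest library for 13 of the 14 markers. Some of them reached 10 reads only through this library.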

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

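Of 95 named genes, 85 of them called, and 39 lists, 18 of them called, no called result reversed under any alternative, and 40 of the 85 gene calls held under every alternative. The 18 list calls did not hold with an estimated correlation in camera, which left 0. The estimate lay below the preset 0.01 in some lost lists (glycolysis -0.018, m6A readers -0.029) and above it in others (mitosis 0.468). In that setting camera also tests on the few residual degrees of freedom of the libraries. The loss therefore cannot show whether correlated genes made the calls. With each library left out in turn the totals ran from 363 to 1130 genes, with 145 to 484 higher and 218 to 646 lower, and with 11 to 18 lists and 3 to 5 panel genes called (18 and 5 with all libraries). Fewer samples make calls harder to reach, but the fall also differed by library. The total was 1130 without day 0 replicate 3 and 363 to 521 without any other library. Of the main calls 864 were kept without day 0 replicate 3, whose other tissue was seen only in the data. Same-numbered deviations from the mean of each age correlated at -0.04, -0.00 and -0.05, so no pairing by number was seen. With 3 libraries per age the deviations are not independent, so these values cannot exclude pairing. The replicate block called 501 genes, 217 higher and 284 lower. limma without the mean-variance trend called 669 (299 and 370). An adjusted p of 0.01 left 312 (143 and 169) and at least a 2-fold change 588 (273 and 315). Quantile normalization called 479 lower, and the medians of 2 uncalled lists changed sign under it (oxidative phosphorylation from -0.14 to 0.06, pericyte and smooth muscle from -0.08 to 0.06). The latter also turned under centring (to 0.03), as did that of macrophages (-0.04 to 0.07), which turned under the scaling without abundant genes too (0.01). Chosen after seeing the data, centring called 492 lower, voom on the recovered reads 1831 (725 higher), with 92.2% of the main calls among them, and the authors' adjusted p 1992 (1058 higher). Beyond the library, threshold and correlation settings, the cause was not tested. Filters, pseudocounts and the scaling without the most abundant genes kept every total within 1.5 times. Depth limits low genes, since 1 read in a gene of 1 kb was 0.0614 to 0.0741 FPKM. The m6A pull-down comparisons were not run here. Of count-based tests only voom on the recovered reads was run, and the test planned for deposited counts was not.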

Other observations

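The tests of other tissue, depth and exchanged labels for day 0 replicate 3 were chosen only after its values were seen. Among lists not described so far, complement genes had 4 of 11 higher and 0 lower (4 higher and 1 lower adjusted over the list alone; median 0.63 relative to all genes, camera adjusted p = 0.00965, adjusted p = 0.323 with an estimated correlation). C7 and C1r, components of the complement cascade, had log2 fold changes of 1.41 and 1.35 (limma adjusted p of 0.0624 without older replicate 2 and 0.0572 without older replicate 3), and Serping1 and Clu were the others, and the list's camera adjusted p was 0.0555 without older replicate 2. Cd74, the invariant chain of class II antigen presentation, rose from 4.69 ± 0.436 to 27.2 ± 1.59 FPKM (SD, n = 3; log2 fold change 2.31, limma adjusted p = 0.000492). It was the 1 called gene of 9 in the antigen presentation list (1 adjusted over the list alone, camera adjusted p = 0.0471, and 0.130 without older replicate 2 and 0.0736 without day 0 replicate 3, also lost without day 0 replicate 1, adjusted p = 0.323 with an estimated correlation). The list of neuregulin, growth factor and receptor genes had 3 of 16 higher (5 adjusted over the list alone, camera adjusted p = 0.0332, and 0.123 without day 0 replicate 2, also lost without day 0 replicate 1 and older replicates 2 and 3 in turn, adjusted p = 0.401 with an estimated correlation, fry adjusted p = 0.0740), with the growth factor gene Fgf1 at 0.76 (limma adjusted p = 0.0156, and 0.0654 without older replicate 1). Tfrc, the transferrin receptor gene, was called at -1.12 (limma adjusted p = 0.0202, and 0.0792 without day 0 replicate 1).

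The hypoxia list had 4 of 18 genes higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.160), with Pdk1 up by 1.01 and Slc2a1 down, and 2 higher and 1 lower without day 0 replicate 3. Hippo pathway genes had 1 of 21 higher and 2 lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.242), and Mob1b, a kinase activator of that pathway, fell by 1.39. Without day 0 replicate 3 that list had 2 higher and 2 lower, the antioxidant list 0 and 0, and the adipocyte list 0 higher. In the circadian clock list 1 of 17 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.242), and Rora, a nuclear receptor gene, rose by 1.399. Antioxidant genes had 1 of 25 higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.282). With limma no interferon response gene passed (0 of 11, and 0 adjusted over the list alone), although 3 had an unadjusted p under 0.05 and voom called 3 higher (camera adjusted p = 0.0673). The list of Igf2 mRNA-binding and Lin28 genes had 2 of 5 lower (4 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0703). In marker lists of platelets (0 of 4, camera adjusted p = 0.631) and of Schwann cells and neurons (0 of 3, camera adjusted p = 0.952) no gene passed in limma or voom, with 1 each at an unadjusted p under 0.05, and the adipocyte list had 1 of 3 higher (2 adjusted over the list alone, camera adjusted p = 0.102). Too few genes were tested for a list test of lymphocyte (1 gene), neutrophil (2), thymus (2) and liver markers (2), where the called gene was Ttr at 1.44 (limma adjusted p of 0.0739 without older replicate 2). Among lists that camera did not call, fry passed as higher for hypoxia (fry adjusted p = 0.0390), circadian clock (0.0313), adipocyte (0.0161) and immediate early genes (0.0161). It passed as lower for Hippo (0.0336), antioxidant (0.0413) and Igf2 mRNA-binding and Lin28 genes (0.00452). Since fry makes no comparison with other genes and the median gene stood at -0.11, a pass as lower can reflect that shift. Relative to all genes the Hippo and antioxidant medians were both -0.08.

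Skeletal muscle and lung transcripts appeared in day 0 replicate 3, which was the highest library for 92.9% of 14 detected markers (without Ckm, which heart also expresses). Detection meant at least 10 reads in all. Sftpc, Sftpb, Sftpa1, Scgb1a1, Tnnc2 and Mylpf reached that only through this library, so the filter itself favoured it for them. For Ager it was only just the highest, at 3.78 FPKM against 3.65 in older replicate 2. Day 0 replicate 3 also held 21 genes with at least 50 reads that had none in the other 5 libraries, against 0 or 1 such genes in each of those. Sequencing depth is argued against, since the median marker was 42.5 times the other day 0 libraries after correction for depth, with a floor of 3 reads. So is an exchange of ages, since 75.8% of the 1130 genes called without this library placed it nearer day 0. The interval of that share, 73.2% to 78.3%, includes the bound set for this question, so the bound was only just passed. Genes of 1 library are also not independent. No older library was out of place as a partner, with mean correlations of 0.917 to 0.925 within its own age and 0.860 to 0.876 with day 0. A candidate explanation is tissue from outside the heart carried into this sample, and no biological explanation was tested.

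More genes were lower than higher in older hearts on the deposited FPKM scale (462 higher, 752 lower), a direction that turned after quantile normalization (620 and 479), after centring (608 and 492) and in the authors' deposited table (1058 and 934). The other tissue in day 0 replicate 3 is argued against as the whole cause. Without this library 484 genes were higher and 646 lower, and the median log2 fold change was -0.13 beside -0.11 with it. The share called higher was 42.8% without it beside 38.1% with it, so a part in the imbalance is not excluded. The 20 genes with the most reads took 20.8% to 23.2% of reads at day 0 and 25.1% to 26.2% in older hearts. The scaling left out mitochondrial and haemoglobin genes and the 20 genes of highest mean FPKM, which need not be the same 20. It moved the median to -0.0559, so that abundant genes may account for part of the shift. That part cannot be told apart from age, since the value lies between the bounds set beforehand (-0.05 and -0.08). Of the 10 splits of the 6 libraries 1, the real one, called as many genes (1214, with at most 2 in any other), and 10 splits are too few for a share under 0.05. Every other split mixed the ages, and calls of both directions were counted together. The splits therefore cannot bear on the direction of the calls.

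Cytosolic ribosomal protein genes were lower in older hearts as a list, with 14 of 28 called lower and 0 higher (camera adjusted p = 3.47e-06, adjusted p = 0.323 with an estimated correlation). Gene length is argued against as the whole cause, since the list median after removing the trend of fold change on length was -0.31 relative to all genes (bootstrap interval -0.40 to -0.15 over genes, which are not independent). The other tissue in day 0 replicate 3 is argued against as well, with a list median log2 fold change, not taken relative to all genes, of -0.46 without it and -0.45 with it. Reads shared with ribosomal protein pseudogenes stay open and cannot be told apart from a change of the genes, because the 338 pseudogenes tested are not named by their parent gene. The difference in age, which the design names, may also account for it and was not tested on its own.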
